A study of Arabidopsis thaliana with 16 samples.

How the data were processed

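Arabidopsis plants of Col-0 and atg2-2 were grown for 21 days at 12 h light, inoculated, and kept at 16 h light, per the labels' protocols. Systemic rosette leaves were taken 12 days after inoculation from 10 plants per genotype and treatment. Libraries were made from 80 ng RNA with a barcoded oligo-dT primer holding 8 random bases and 12 PCR cycles, per the labels' protocols. Whether reads sharing the random bases were collapsed is not stated.

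Reads were trimmed with Trim Galore, aligned with STAR and quantified with Salmon against TAIR10, and DESeq2 was used for testing, per the submitters' processing notes, which give no versions. The deposited gene tables hold estimated counts (expected counts per gene from Salmon, not whole numbers) and TPM made by the authors. The number of table columns that belonged to no labelled sample was 0. The labels gave 16 libraries in 6 groups, with 2 mock libraries per genotype and 3 libraries per genotype and virus. The same samples were used by the submitters for proteomics, which is not analysed here. Genes of chromosomes 1 to 5 were analysed, and plastid and mitochondrial genes are not analysed here. Names came from the reference annotation, in which all 32544 genes of the table were matched by locus code, and no coordinates were used.

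The estimated counts were rounded and tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F-test. Genes were kept by filterByExpr on the groups, which left 18044 of 32544. Libraries were scaled by TMM, and a group-means model was fitted to all 16 libraries with 10 residual degrees of freedom, since mock groups of 2 give little information on spread alone. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold threshold. The 11 comparisons were each virus with mock per genotype, the genotypes in each treatment, the interaction of each virus with genotype, and TCV with TYMV per genotype. Levels are CPM on TMM-scaled library sizes.

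Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists within a comparison. The 22 lists held 460 genes, 434 of them tested, in 16 response lists and 6 lists of cell type markers. The response lists covered salicylic acid, pattern-triggered immunity, jasmonate and ethylene, RNA silencing, autophagy, photosynthesis, leaf senescence, endoplasmic reticulum folding, heat shock proteins, mitochondrial dysfunction, peroxisome, proteasome, abscisic acid, glucosinolate, anthocyanin and circadian clock. The marker lists covered phloem, guard cells, epidermis, dividing cells, flowers and roots. Of these, 21 had at least 5 tested members and entered the test, and root markers had 1. Members were also counted when adjusted over the list alone. Camera with an estimated correlation and fry served as checks, with a list's median also computed with genes at 0 counts set to their bound.

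The lists, the comparisons, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names ATG2, then the 3 largest increases and 3 largest decreases per comparison among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. For interactions the overlap condition was left out. In virus against mock it adds the 3 members with the smallest p of each called list and 1 of each other list, and in other comparisons 2 of each called list. Where a group had 0 counts, the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% counting interval. Alternatives were DESeq2 1.42.0 (Wald test), RLE scaling, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, a fit to the compared groups alone, limma with a trend on log2(TPM + 1) and log2(TPM + 0.1), an added threshold of 1 in log2 fold change, and leaving out each library in turn. Fits without the virus-abundant genes, fits with genes of at least 5 CPM in mock, the overlaps between genotypes, and overlaps of the viruses with 1 mock library each were added after the data were seen. Where a group keeps 1 library after leaving out the other, that library is assumed to vary like the rest.

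Recovery at this depth was tested on simulated data in which 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The real comparisons with virus called far more genes. The cutoff after Benjamini-Hochberg adjustment depends on how many genes change, so recovery there may be higher than the simulated percentages. The changed genes were drawn from those with at least 10 CPM in Col-0 mock, so recovery at lower levels was not measured. With 18044 genes simulated on the comparison of genotypes in mock, edgeR recovered 13.4% of genes changed 1.5-fold, 50.7% at 2-fold and 95.5% at 4-fold, with 13 false calls. With 18044 genes simulated on TCV against mock in Col-0 the percentages were 10.4, 58.2 and 95.5, with 16 false calls. With 18044 genes simulated on the genotypes in TCV they were 16.4, 64.2 and 97, with 7 false calls. With 18044 genes simulated on the TCV interaction they were 0, 20.9 and 84.8, with 7 false calls. The common biological coefficient of variation was 0.185. DESeq2 left some adjusted p-values as missing, and these stayed missing.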

Results

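Systemic rosette leaves of Arabidopsis thaliana were profiled by 3' tag RNA sequencing 12 days after rub inoculation with infected sap or mock treatment. The viruses were turnip crinkle virus (TCV) and turnip yellow mosaic virus (TYMV), both positive-strand RNA viruses of plants. The genotypes were the wild-type accession Col-0 and atg2-2, a mutant of ATG2, a gene of the core autophagy machinery. Each genotype had 2 mock, 3 TCV and 3 TYMV libraries, 16 in all, in 6 groups. The series title places the experiment in a study of selective autophagy and of the damage that viruses cause. Total counts were 3.21 to 3.28 M in Col-0 mock, 1.72 to 2.49 M in Col-0 TCV and 2.26 to 2.91 M in Col-0 TYMV. They were 2.39 to 3.71 M in atg2-2 mock, 1.34 to 2.17 M in atg2-2 TCV and 1.86 to 2.64 M in atg2-2 TYMV. Levels are given as mean ± SD of CPM on normalised library sizes, with n = 2 for mock and n = 3 for each virus group. Fold changes are log2 values ± SE, and counts of list members "adjusted over the list alone" stand in brackets. The digit after AT in each locus code is the chromosome. Largest increases and decreases are ranked among the called genes that the naming rule in the methods admits. The labels do not say that replicates came from separately grown or separately inoculated plants, so p-values measure the spread between these libraries, which may be technical. Counting intervals and floors cover counting error only.

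Libraries separated first by virus. The first principal component of log2 CPM held 47.9% of the variance and the second 21.6%. TCV libraries of both genotypes had first-component scores between 63.42 and 127.8, whereas all mock and TYMV libraries lay between -68.8 and -32.01. Mock libraries of the genotypes lay together. Replicates of a group correlated with Pearson r of 0.935 to 0.975 across tested genes, which are not independent replicates, and every pair differed by more than counting noise (chi-square per degree of freedom 2.5 to 11.8).

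**Figure D1:**
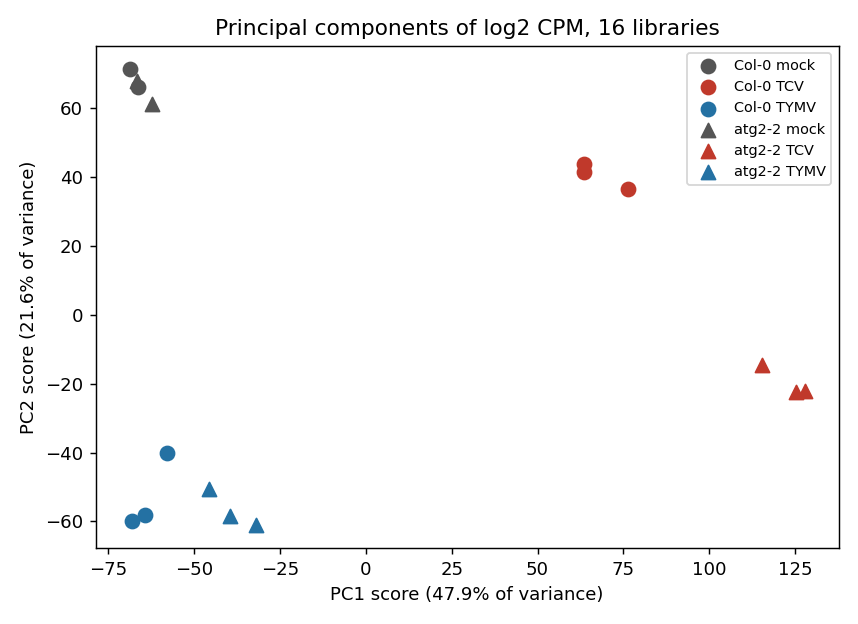
Scores of the 16 libraries on the first (x axis, 47.9% of variance) and second (y axis, 21.6%) principal components of log2 CPM, 1 point per library, with circles for Col-0, triangles for atg2-2 and a colour per treatment. The 4 mock libraries overlap at second-component scores of 61.08 to 71.32, and the atg2-2 TCV libraries lie at first-component scores of 115.4 to 127.8, beyond the Col-0 TCV libraries at 63.42 to 76.26.

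Part of the counts in infected leaves went to genes with far lower counts in mock. By a rule set after the data were seen, 107 genes had at least 20 CPM and at least 30 times the mock CPM plus 1 in every TCV library, 38 genes did so in every TYMV library, and 0 did so in both. The 107 genes took 17.9 to 19.6% of the counts in Col-0 TCV and 20.7 to 25.7% in atg2-2 TCV, against 0.0438 to 0.0514% in the mock libraries of Col-0 and 0.048 to 0.0502% in those of atg2-2. The 38 genes took 1.62 to 4.69% in Col-0 TYMV and 1.12 to 1.79% in atg2-2 TYMV. Of the members of the fixed gene lists, 1 was in these sets, the senescence-associated transcription factor WRKY75 (AT5G13080). Genes of the sets are named as TCV-abundant or TYMV-abundant where they occur.

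**Figure D2:**
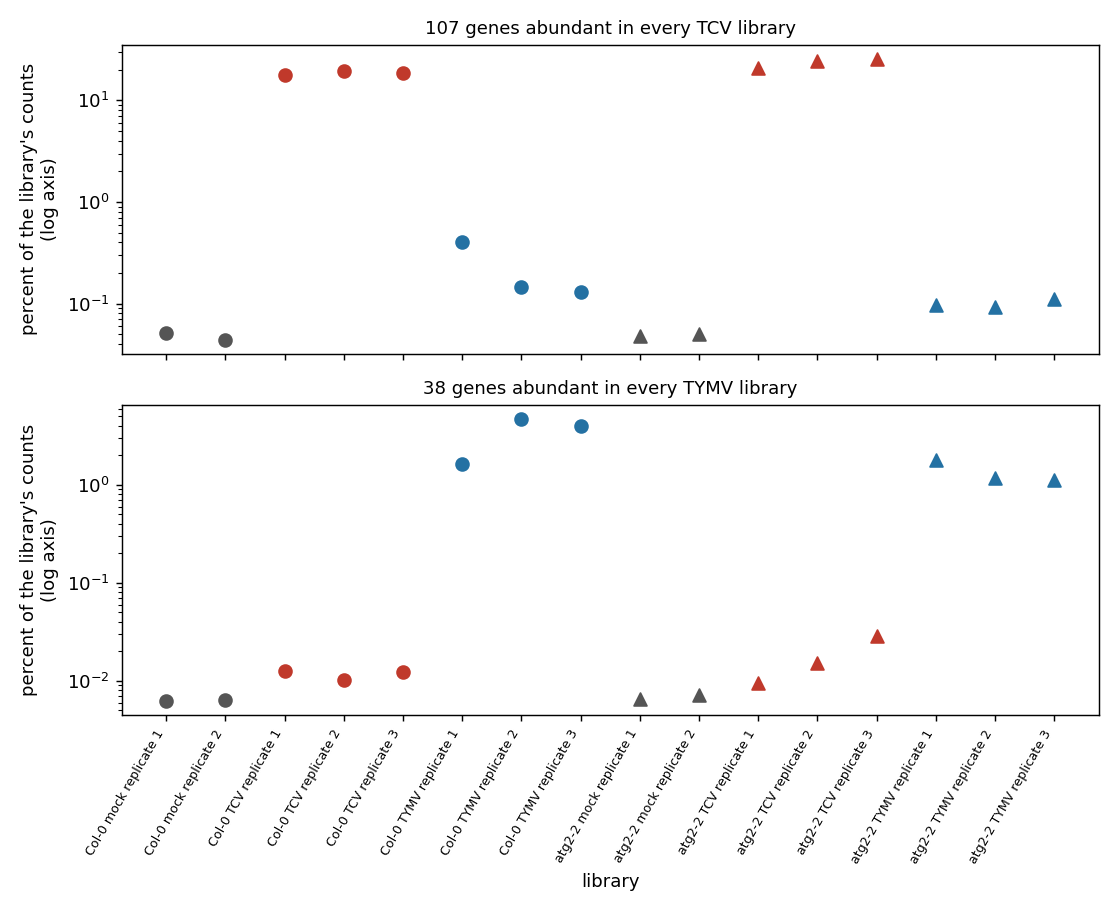
Percent of each library's counts (y axis, log scale) taken by the 107 TCV-abundant genes (top) and the 38 TYMV-abundant genes (bottom), 1 point per library along the x axis, with circles for Col-0 and triangles for atg2-2. In Col-0 TYMV replicate 1 the 107 genes took 0.402%, against 0.13 and 0.147% in the other replicates of that group.

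ATG2 (AT3G19190) was measured in every group. Its level was 10.4 ± 2.28 CPM in Col-0 mock, 10.6 ± 1.89 in Col-0 TCV, 22.4 ± 3.63 in Col-0 TYMV, 7.16 ± 0.0734 in atg2-2 mock, 13.8 ± 2.55 in atg2-2 TCV and 12.6 ± 1.62 in atg2-2 TYMV. A 3' tag counts transcript ends and does not check the atg2-2 lesion. The genotypes were not distinguished by this gene in mock (log2 fold change -0.54 ± 0.31, edgeR adjusted p = 1) or TCV (0.37 ± 0.26, 0.35). It was lower in atg2-2 in TYMV (-0.83 ± 0.22, edgeR adjusted p = 0.021), a call lost in 6 of 26 alternatives, where adjusted p ranged from 0.019 to 0.3. In Col-0 it rose with TYMV (1.1 ± 0.26, edgeR adjusted p = 0.0038, but 0.087 without Col-0 mock replicate 1) and differed by 0.04 ± 0.28 with TCV. In atg2-2 it rose with TCV (0.94 ± 0.30, edgeR adjusted p = 0.014, lost in 6 of 26 alternatives at up to 0.14) and with TYMV (0.81 ± 0.28, edgeR adjusted p = 0.044, lost in 12 of 26 at up to 0.2). The interaction tests of ATG2 gave edgeR adjusted p = 0.21 for TCV and 0.91 for TYMV.

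To see what TCV changed in wild-type leaves, Col-0 TCV was compared with Col-0 mock. Nuclear-encoded photosynthesis genes were lower, with 43 of 46 tested members down (43 adjusted over the list alone) and a median log2 fold change of -1.52 (camera adjusted p = 1.76e-29, adjusted p = 0.174 with an estimated correlation). The light-harvesting gene LHCB2.3 (AT3G27690) went from 1560 ± 86 to 183 ± 21 CPM (-3.09 ± 0.21, edgeR adjusted p = 2.3e-09). The photosystem I genes PSAD-2 (AT1G03130) and LHCA3 (AT1G61520) changed by -1.89 ± 0.13 and -1.82 ± 0.13. PORA (AT5G54190), which encodes a chlorophyll synthesis enzyme, changed by -4.25 ± 0.25 and was among the 3 largest decreases, with AT3G16670 (-4.53 ± 0.31) and AT5G44260 (-4.35 ± 0.63). Dividing cell markers were lower, with 5 of 12 down (5 adjusted over the list alone; camera adjusted p = 0.0254, adjusted p = 0.174 with an estimated correlation), among them the cytokinesis syntaxin SYP111 (AT1G08560) at -1.70 ± 0.23.

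Pigment and defence metabolism moved the other way in the same leaves. Of 12 anthocyanin and flavonoid genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.000359, adjusted p = 0.114 with an estimated correlation). DFR (AT5G42800) and LDOX (AT4G22880), enzymes of anthocyanin synthesis, rose by 4.2 ± 0.54 and 3.5 ± 0.56, and GSTF12 (AT5G17220), needed for anthocyanin storage, by 2.83 ± 0.39. Of 22 glucosinolate genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00765, adjusted p = 0.461 with an estimated correlation). The synthesis genes CYP79B3 (AT2G22330) and BCAT4 (AT3G19710) rose by 3.10 ± 0.26 and 2.82 ± 0.32, and those that fell were the myrosinases, which break glucosinolates down, TGG2 (AT5G25980) at -1.66 ± 0.15 and TGG1 at -1.25 (TGG1 was named after its value was seen).

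Hormone and stress lists rose in part. In the jasmonate and ethylene list 12 of 28 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 0.00331, adjusted p = 0.187 with an estimated correlation), with CORI3 (AT4G23600) at 2.16 ± 0.25, the jasmonate synthesis gene AOC1 (AT3G25760) at 2.74 ± 0.45 and the transcription factor MYC2 (AT1G32640) at 1.15 ± 0.19. In the mitochondrial dysfunction response 5 of 14 rose (7 adjusted over the list alone; camera adjusted p = 0.00331, adjusted p = 0.114 with an estimated correlation), including UPOX (AT2G21640) at 1.91 ± 0.28 and the alternative oxidase AOX1A (AT3G22370) at 1.01 ± 0.22. Leaf senescence genes went both ways, 6 up and 3 down of 21 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0459 upward, adjusted p = 0.483 with an estimated correlation). SAG29 (AT5G13170) and SAG21 (AT4G02380) rose by 2.92 ± 0.28 and 1.55 ± 0.20, and the TCV-abundant WRKY75 went from 0.49 ± 0.693 to 104 ± 16.1 CPM, a ratio with a counting interval of 70.5 to 1010. The 3 that fell, named after their values were seen, were SEN1 (-2.20), ASN1 (-1.71) and DIN10 (-1.36). Pattern-triggered immunity and camalexin genes passed narrowly, with 5 of 16 up and 1 down (6 and 1 adjusted over the list alone; camera adjusted p = 0.0498, adjusted p = 0.296 with an estimated correlation), WRKY18 (AT4G31800) rising by 1.98 ± 0.22 and the NADPH oxidase gene RBOHD (AT5G47910) by 1.28 ± 0.29.

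Other lists were not called in this comparison but held large single changes. In RNA silencing 4 of 17 rose (4 adjusted over the list alone; camera adjusted p = 0.103), and ARGONAUTE gene AGO1 (AT1G48410) went from 72.2 ± 10.6 to 250 ± 31.5 CPM (1.79 ± 0.14, edgeR adjusted p = 2.1e-08). Of 28 salicylic acid genes 7 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.118), with AED1 (AT5G10760) at 1.72 ± 0.20. Of 42 autophagy genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.14), with ATG13B (AT3G18770) at 3.58 ± 0.39. The homeodomain gene PDF2 (AT4G04890), an epidermis marker, rose by 4.12 ± 0.28, and the glyoxylate-cycle gene MLS (AT5G03860) by 3.77 ± 0.38. The root iron transporter IRT1 (AT4G19690), the 1 root marker tested, rose by 3.35 ± 0.27. The 3 largest increases were TCV-abundant genes with 0 counts in Col-0 mock, namely AT4G17200 (at least 4150-fold higher), AT1G09673 (at least 758-fold) and ALE1 (AT1G62340, at least 484-fold), against a floor of 3 counts over the group. In all, edgeR called 5060 of 18044 tested genes, 2519 higher and 2541 lower, and 8 of 21 lists. With a log2 fold change of at least 1 the split was 1945 higher and 1081 lower. Without Col-0 mock replicate 1 the counts were 3319 genes and 3 lists.

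TYMV in wild-type leaves was examined by comparing Col-0 TYMV with Col-0 mock. All 46 photosynthesis genes tested were lower (46 adjusted over the list alone), with a median of -2.03 (camera adjusted p = 1.15e-54, adjusted p = 0.0888 with an estimated correlation). The antenna gene LHCB6 (AT1G15820) went from 4860 ± 265 to 791 ± 36.5 CPM (-2.62 ± 0.14, edgeR adjusted p = 6.1e-10), PSAD-2 changed by -2.79 ± 0.13 and the oxygen-evolving complex gene PSBP-1 (AT1G06680) by -2.33 ± 0.13. Heat shock protein genes were higher, 10 of 19 (11 adjusted over the list alone; median 2.32, camera adjusted p = 3.92e-05, adjusted p = 0.243 with an estimated correlation). HSP70 (AT3G12580) rose by 2.73 ± 0.49 and HSC70-3 (AT3G09440) by 0.81 ± 0.14, and HSP17.6A (AT5G12030), with 0 counts in Col-0 mock, was at least 15.3-fold higher at 7.63 ± 3.06 CPM. The mitochondrial dysfunction response rose in 7 of 14 (7 adjusted over the list alone; camera adjusted p = 8.4e-05, adjusted p = 0.0569 with an estimated correlation), with UPOX at 3.01 ± 0.27, BCS1 (AT3G50930) at 1.69 ± 0.28 and AOX1A at 1.36 ± 0.21.

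Autophagy genes rose in 10 of 42 and fell in 1 (11 and 1 adjusted over the list alone; median 0.42, camera adjusted p = 0.000948, adjusted p = 0.144 with an estimated correlation). The ubiquitin-like ATG8B (AT4G04620) and ATG8E (AT2G45170) rose by 1.60 ± 0.20 and 1.24 ± 0.19. Of the jasmonate and ethylene list 10 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00541, adjusted p = 0.243 with an estimated correlation). The plant defensin PDF1.2 (AT5G44420) went from 7.68 ± 7.16 to 162 ± 22.1 CPM (4.40 ± 0.46, edgeR adjusted p = 7.4e-07), although its near-identical copies can share reads and make the value of each uncertain. The 2 that fell, named after their values were seen, were AOS (-1.45) and AOC2 (-0.91), both enzymes of jasmonate synthesis. Salicylic acid genes rose in 10 of 28 and fell in 1 (13 and 2 adjusted over the list alone; camera adjusted p = 0.0128, adjusted p = 0.474 with an estimated correlation), with the pathogenesis-related gene PR1 (AT2G14610) at 1.67 ± 0.24 and SAG101 (AT5G14930) at 1.24 ± 0.20. Pattern-triggered immunity genes rose in 4 of 16 (4 adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.243 with an estimated correlation), with MPK3 (AT3G45640) at 0.96 ± 0.17 and WRKY40 (AT1G80840) at 2.41 ± 0.43.

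Senescence genes were not called as a list, with 5 of 21 up and 5 down (5 and 5 adjusted over the list alone; camera adjusted p = 0.779), and DIN10 (AT5G20250) changed by -1.09 ± 0.18. The catalase gene CAT2 (AT4G35090) rose by 1.18 ± 0.15, the proteasome subunit gene RPN2A (AT2G32730) by 0.94 ± 0.16 and the phloem marker FTIP1 (AT5G06850) by 4.75 ± 0.44. The 3 largest decreases were IAA29 (AT4G32280, -5.30 ± 0.53), an auxin response gene, PORA (-5.29 ± 0.26) and AT2G14247 (-4.95 ± 0.41). The 3 largest increases were TYMV-abundant genes with 0 counts in Col-0 mock: AT2G13150 (at least 1780-fold higher), AT5G09030 (at least 1640-fold) and FOA1 (AT3G17320, at least 836-fold). In all, edgeR called 3860 genes, 1932 higher and 1928 lower, and 7 lists, against 2268 genes and 4 lists without Col-0 mock replicate 1. On the log2(TPM + 1) scale, without TMM scaling, the split was 2454 higher and 977 lower, and the median of all genes moved from 0.02 to 0.19.

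The response to TCV in the autophagy mutant was measured by comparing atg2-2 TCV with atg2-2 mock. Of 28 salicylic acid genes 26 rose and 1 fell (26 and 1 adjusted over the list alone; median 1.48, camera adjusted p = 3.69e-08, adjusted p = 0.0997 with an estimated correlation). PR1 went from 177 ± 7.96 to 2590 ± 593 CPM (3.87 ± 0.27, edgeR adjusted p = 1e-09). CBP60G (AT5G26920), a regulator of salicylic acid synthesis, rose by 4.1 ± 0.30 and the salicylic acid hydroxylase gene DLO1 (AT4G10500) by 2.97 ± 0.21. Of 21 senescence genes 19 rose and 1 fell (19 and 1 adjusted over the list alone; median 3.39, camera adjusted p = 1.73e-08, adjusted p = 0.0898 with an estimated correlation). SAG13 (AT2G29350) went from 12.7 ± 4.57 to 421 ± 37.7 CPM (5.00 ± 0.30, edgeR adjusted p = 1.8e-10), the chlorophyll breakdown gene NYE1 (AT4G22920) rose by 4.37 ± 0.26 and SAG21 by 3.42 ± 0.22. Autophagy genes rose in 27 of 42 and fell in 0 (28 and 0 adjusted over the list alone; median 0.96, camera adjusted p = 1.02e-06, adjusted p = 0.0712 with an estimated correlation), with ATG8H (AT3G06420) at 4.16 ± 0.25, ATG13B at 5.05 ± 0.42 and APG8A (AT4G21980) at 2.00 ± 0.17.

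Photosynthesis genes were lower in all 46 tested (46 adjusted over the list alone; median -2.27, camera adjusted p = 7.74e-29, adjusted p = 0.0997 with an estimated correlation). PSAN (AT5G64040), PSBQ-2 (AT4G05180) and PSAF (AT1G31330) changed by -3.27 ± 0.16, -2.85 ± 0.13 and -2.69 ± 0.13. Dividing cell markers were lower in 8 of 12 (8 adjusted over the list alone; camera adjusted p = 0.00527, adjusted p = 0.0898 with an estimated correlation). The replication clamp gene PCNA1 (AT1G07370) changed by -1.90 ± 0.35. Guard cell and stomatal lineage markers were lower in 5 of 9 (6 adjusted over the list alone; camera adjusted p = 0.0352, adjusted p = 0.0997 with an estimated correlation). The stomatal receptor gene TMM (AT1G80080) changed by -1.97 ± 0.46. Epidermis and cuticle markers were lower in 8 of 10 and higher in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0359, adjusted p = 0.141 with an estimated correlation). The lipid transfer protein gene LP1 (AT2G38540) changed by -1.47 ± 0.13, and the exception was PDF2 at 4.8 ± 0.29.

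Stress lists were higher in the same leaves. Pattern-triggered immunity rose in 12 of 16 and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.000688, adjusted p = 0.0898 with an estimated correlation), with WRKY18 at 2.89 ± 0.23 and the camalexin synthesis gene PAD3 (AT3G26830) at 3.62 ± 0.48. Endoplasmic reticulum folding genes rose in 12 of 23 (15 adjusted over the list alone; camera adjusted p = 0.00137, adjusted p = 0.0997 with an estimated correlation), with the cell death suppressor BI1 (AT5G47120) at 1.33 ± 0.12 and BZIP60 (AT1G42990) at 1.26 ± 0.17. Heat shock genes rose in 12 of 19 and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.00137, adjusted p = 0.193 with an estimated correlation). HSP70 changed by 2.99 ± 0.49. The mitochondrial list rose in 9 of 14 (10 adjusted over the list alone; camera adjusted p = 0.0016, adjusted p = 0.0898 with an estimated correlation). Its alternative oxidase AOX1D (AT1G32350) went from 0.142 ± 0.201 to 111 ± 19.6 CPM, a ratio with a counting interval of 117 to 25800. Abscisic acid and drought genes rose in 8 of 16 and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00527, adjusted p = 0.163 with an estimated correlation), with RD20 (AT2G33380) at 6.05 ± 0.34 and the phosphatase gene HAI1 (AT5G59220) at 3.76 ± 0.69.

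Jasmonate and ethylene genes rose in 14 of 28 and fell in 6 (14 and 6 adjusted over the list alone; camera adjusted p = 0.0389 upward, adjusted p = 0.235 with an estimated correlation). JAZ1 (AT1G19180), a repressor of jasmonate signalling, rose by 3.36 ± 0.32 and PR4 (AT3G04720) by 2.60 ± 0.26, whereas PDF1.2, named here after its value was seen, changed by -2.98 ± 0.55. AGO1 rose by 1.66 ± 0.14, the myrosinase TGG2 changed by -2.68 ± 0.16 and IRT1 rose by 4.29 ± 0.29. The largest increases were the TCV-abundant AT3G26140 (at least 7560-fold higher), AT2G04500 (at least 7400-fold) and AT4G17200 (at least 1140-fold), all with 0 counts in atg2-2 mock. The largest decreases were AT5G50650 (at least 23.8-fold lower, shared with its copy AT5G50550 and lost under DESeq2 at adjusted p = 0.087), MSRB6 (AT4G04840, -6.60 ± 0.32), a methionine sulfoxide reductase, and AT3G50560 (from 15.1 ± 4.11 to 0.187 ± 0.324 CPM, a ratio with a counting interval of 11.8 to 2690). In all, edgeR called 8317 genes, 4316 higher and 4001 lower, and 13 lists. On the log2(TPM + 1) scale the split turned to 3727 higher and 4502 lower.

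TYMV in the mutant was assessed by comparing atg2-2 TYMV with atg2-2 mock. Salicylic acid genes rose in 25 of 28 (26 adjusted over the list alone; median 1.62, camera adjusted p = 1.68e-16, adjusted p = 0.0328 with an estimated correlation). PR1 went from 177 ± 7.96 to 1890 ± 485 CPM (3.41 ± 0.26, edgeR adjusted p = 2.7e-08), DLO1 rose by 3.24 ± 0.21 and CBP60G by 3.40 ± 0.30. Senescence genes rose in 16 of 21 and fell in 1 (16 and 1 adjusted over the list alone; median 2.27, camera adjusted p = 8.18e-10, adjusted p = 0.0499 with an estimated correlation), with SAG13 at 3.40 ± 0.29, SAG21 at 2.27 ± 0.20 and the blue copper protein gene BCB (AT5G20230) at 2.62 ± 0.27. Autophagy genes rose in 18 of 42 (18 adjusted over the list alone; median 0.63, camera adjusted p = 4.34e-07, adjusted p = 0.0295 with an estimated correlation), with ATG8H at 3.81 ± 0.25, ATG8E at 1.85 ± 0.19 and APG8A at 1.75 ± 0.17. All 46 photosynthesis genes were lower (46 adjusted over the list alone; median -1.91, camera adjusted p = 1.07e-47, adjusted p = 0.0499 with an estimated correlation), with LHCB6 at -2.37 ± 0.14, PSAD-2 at -2.22 ± 0.13 and PSBP-1 at -2.19 ± 0.13.

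Pattern-triggered immunity rose in 11 of 16 (12 adjusted over the list alone; camera adjusted p = 9.93e-06, adjusted p = 0.0328 with an estimated correlation), with WRKY40 at 3.05 ± 0.48 and the wall-associated kinase WAK1 (AT1G21250) at 0.94 ± 0.17. The mitochondrial list rose in 8 of 14 (10 adjusted over the list alone; camera adjusted p = 6.13e-06, adjusted p = 0.0295 with an estimated correlation), with UPOX at 2.31 ± 0.27 and BCS1 at 2.21 ± 0.29. Heat shock genes rose in 12 of 19 (14 adjusted over the list alone; camera adjusted p = 1.93e-06, adjusted p = 0.101 with an estimated correlation). The co-chaperone gene ROF2 (AT5G48570) changed by 1.82 ± 0.32. Jasmonate and ethylene genes rose in 11 of 28 and fell in 2 (16 and 3 adjusted over the list alone; camera adjusted p = 0.00157, adjusted p = 0.123 with an estimated correlation), with PR4 at 1.78 ± 0.25 and the defensin copy PDF1.2c (AT5G44430) at 4.02 ± 0.38. Endoplasmic reticulum folding genes rose in 5 of 23 (5 adjusted over the list alone; camera adjusted p = 0.0106, adjusted p = 0.198 with an estimated correlation). BZIP60 changed by 1.07 ± 0.17. Epidermis and cuticle markers were lower in 7 of 10 (9 adjusted over the list alone; camera adjusted p = 0.00281, adjusted p = 0.0499 with an estimated correlation). The wax gene CER1 (AT1G02205) changed by -0.91 ± 0.17. PORA changed by -5.19 ± 0.28 and IAA29 by -3.42 ± 0.49, followed by AT4G38825 (-3.21 ± 0.46). The largest increases were AT5G01215 (at least 300-fold higher) and AT3G01735 (at least 215-fold), both TYMV-abundant, and AT3G11920 (at least 198-fold, at 114 ± 134 CPM), all with 0 counts in atg2-2 mock. Over all tested genes edgeR called 4441 genes, 2206 higher and 2235 lower, and 10 lists, with 2883 genes without atg2-2 mock replicate 1 and 2811 without replicate 2. On the log2(TPM + 1) scale the split was 3531 higher and 1088 lower.

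**Figure D3:**
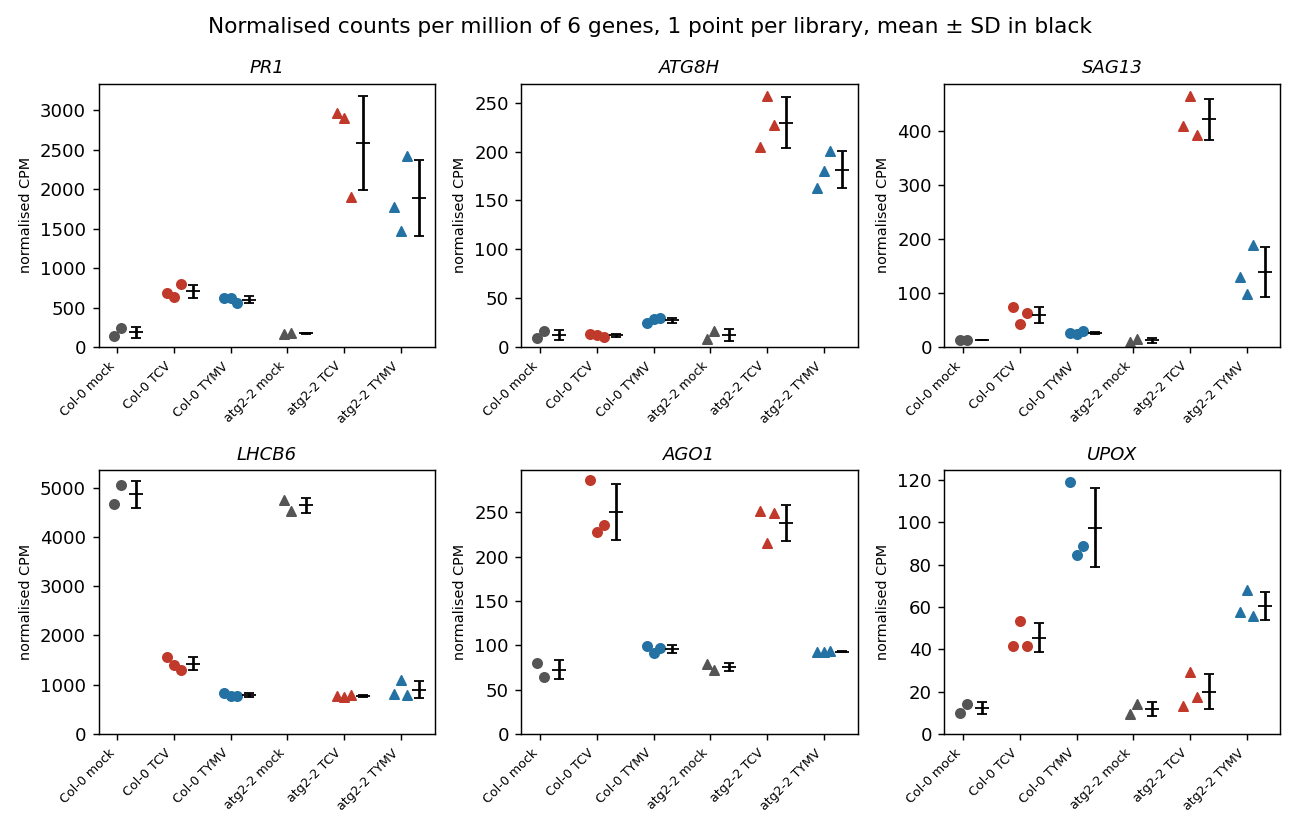
Normalised CPM (y axes, linear from 0) of 6 genes in the 6 groups (x axes), 1 point per library, with the group mean ± SD in black (n = 2 for mock, n = 3 for each virus). PR1 lies at 1900 to 2960 CPM in atg2-2 TCV against 631 to 798 in Col-0 TCV, and ATG8H at 205 to 257 against 10.4 to 13.5.

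Without virus few genes were called between the genotypes. In atg2-2 mock against Col-0 mock edgeR called 7 genes, 5 higher and 2 lower, and 945 had an unadjusted p under 0.05. The higher genes named by the fixed rule were AT1G75945 (14.5 ± 3.98 against 0.508 ± 0.256 CPM, a ratio with a counting interval of 9.99 to 149), AT1G04770 (1.87 ± 0.26) and APR3 (AT4G21990, 1.52 ± 0.23), which encodes a sulfate assimilation enzyme. These 3 calls were lost without Col-0 mock replicate 1, where the log2 fold changes were 4.32, 1.81 and 1.69, against 4.74, 1.87 and 1.52 with all libraries. AT1G75945 and AT1G04770 were also lost without atg2-2 mock replicate 2 (log2 fold changes 4.41 and 1.84). APR3 was lost without Col-0 mock replicate 2 (1.37) or atg2-2 mock replicate 1 (1.28). The remaining 2, named after their values were seen, were APR1, of the same enzyme family, and the vacuolar processing enzyme GAMMA-VPE (AT4G32940, 1.36 ± 0.15). APR1 was lost without Col-0 mock replicate 1 (edgeR adjusted p = 0.23), atg2-2 mock replicate 1 (0.12) or atg2-2 mock replicate 2 (0.071), and GAMMA-VPE was kept whichever mock library was left out. AT2G01422 (1.1 ± 0.353 against 76.4 ± 6.35 CPM, -6.12 ± 0.38, edgeR adjusted p = 5.8e-08) and AT5G24240 (-5.17 ± 0.53) were lower, the first at adjusted p = 0.061 with limma on log2(TPM + 0.1). No list member was called by edgeR in any list. Camera called 5 lists upward by small medians: jasmonate and ethylene (4 members adjusted over the list alone; median 0.48, or 0.40 with members at 0 counts set to their bound; camera adjusted p = 2.01e-07, adjusted p = 0.09 with an estimated correlation), autophagy (0 adjusted over the list alone; 0.0296 and 0.373), glucosinolate (0 adjusted over the list alone; 0.0329 and 0.549), anthocyanin (1 adjusted over the list alone; 0.0329 and 0.373) and phloem markers (2 adjusted over the list alone; 0.039 and 0.51). Without Col-0 mock replicate 2 the counts were 23 genes and 9 lists, and the lists numbered 3 without Col-0 mock replicate 1 and 1 without atg2-2 mock replicate 2. The gene count was 18 with DESeq2, 89 without the filter on low counts and 23 with only the compared groups, and the split was 6 higher and 4 lower on the log2(TPM + 0.1) scale. Without Col-0 mock replicate 1 the split turned to 1 higher and 4 lower, and without Col-0 mock replicate 2 it was 14 higher and 9 lower.

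Under TCV the genotypes differed widely. Autophagy genes were higher in atg2-2 than in Col-0 in 27 of 42 and lower in 0 (28 and 0 adjusted over the list alone; median 0.87, camera adjusted p = 2.6e-11, adjusted p = 0.0102 with an estimated correlation). ATG8H lay at 230 ± 26.4 against 11.9 ± 1.56 CPM (4.25 ± 0.22, edgeR adjusted p = 8.4e-10) and ATG8E was higher by 2.57 ± 0.18. Senescence genes were higher in 18 of 21 (19 adjusted over the list alone; median 2.1, camera adjusted p = 5.49e-14, adjusted p = 0.0533 with an estimated correlation), with the smallest p for NYE1 at 4.30 ± 0.23 and the chlorophyll b reductase gene NYC1 (AT4G13250) at 2.1 ± 0.16. Salicylic acid genes were higher in 21 of 28 (23 adjusted over the list alone; median 1.18, camera adjusted p = 6.21e-12, adjusted p = 0.0542 with an estimated correlation), with DLO1 at 3.37 ± 0.20 and PBS3 (AT5G13320), a salicylic acid synthesis gene, at 3.21 ± 0.29. Abscisic acid genes were higher in 10 of 16 (11 adjusted over the list alone; camera adjusted p = 3.7e-06, adjusted p = 0.0542 with an estimated correlation), with RD20 at 4.94 ± 0.27 and the transcription factor RD26 (AT4G27410) at 3.36 ± 0.36.

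Photosynthesis genes were lower in the infected mutant in 44 of 46 (44 adjusted over the list alone; median -0.84, camera adjusted p = 8.74e-21, adjusted p = 0.154 with an estimated correlation). The Rubisco small subunit genes RBCS1B (AT5G38430) and RBCS2B (AT5G38420) differed by -2.07 ± 0.15 and -1.94 ± 0.15, with near-identical sequences that make the value of each uncertain. Glucosinolate genes were lower in 12 of 22 and higher in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.0076, adjusted p = 0.325 with an estimated correlation). IMD1 (AT5G14200) differed by -1.51 ± 0.21. The 3 that were higher, named after their values were seen, were CYP79B2 (0.95), MYB51 (1.31) and BCAT4 (1.39). Anthocyanin genes were lower in 4 of 12 (4 adjusted over the list alone; camera adjusted p = 0.00802, adjusted p = 0.0808 with an estimated correlation). Chalcone synthase TT4 (AT5G13930) differed by -1.21 ± 0.20. Epidermis markers were lower in 6 of 10 and higher in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00164, adjusted p = 0.0542 with an estimated correlation). LP1 differed by -1.37 ± 0.12. Dividing cell markers were lower in 2 of 12, PCNA1 at -1.57 ± 0.34 and the cell cycle kinase CDKB2 (AT1G76540) at -1.35 ± 0.34 (2 adjusted over the list alone; camera adjusted p = 0.0166, adjusted p = 0.0808 with an estimated correlation).

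Further lists were higher in the mutant under TCV. Pattern-triggered immunity had 9 of 16 higher (9 adjusted over the list alone; camera adjusted p = 2.47e-05, adjusted p = 0.0533 with an estimated correlation). WRKY33 (AT2G38470) differed by 1.88 ± 0.28. Heat shock genes had 8 of 19 higher (8 adjusted over the list alone; camera adjusted p = 0.00157, adjusted p = 0.198 with an estimated correlation). HSP70 differed by 2.18 ± 0.42. Jasmonate genes had 8 of 28 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0087, adjusted p = 0.165 with an estimated correlation). JAZ1 differed by 2.41 ± 0.26. Endoplasmic reticulum folding genes had 6 of 23 higher (6 adjusted over the list alone; camera adjusted p = 0.0087, adjusted p = 0.165 with an estimated correlation). BI1 differed by 1.06 ± 0.11. Peroxisome genes had 11 of 35 higher and 2 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.0166, adjusted p = 0.073 with an estimated correlation). The fatty acid oxidation gene PKT3 (AT2G33150) differed by 1.13 ± 0.11. Single genes with the largest differences were AT3G61930 (at least 58.3-fold higher), DMP1 (AT3G21520, a mean of 87 against 0.153 CPM, ratio interval 86.1 to 19100) and AT1G11925 (at least 36.7-fold higher), and on the lower side AT3G46490 (at least 20-fold), AT2G01422 (-6.50 ± 0.33) and MSRB6 (-4.01 ± 0.39). Over all tested genes edgeR called 4630 genes, 2297 higher and 2333 lower, and 14 lists. On the log2(TPM + 0.1) scale the split was 1871 higher and 2915 lower.

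Under TYMV the genotypes also differed. Senescence genes were higher in atg2-2 in 17 of 21 (19 adjusted over the list alone; median 2.27, camera adjusted p = 1.07e-22, adjusted p = 0.016 with an estimated correlation). The asparagine synthetase gene ASN1 (AT3G47340) lay at 111 ± 43.9 against 4.01 ± 3.31 CPM (4.86 ± 0.37, edgeR adjusted p = 1e-07), SAG13 was higher by 2.37 ± 0.22 and the senescence protease gene SAG12 (AT5G45890) by 6.12 ± 0.58. Salicylic acid genes were higher in 22 of 28 (24 adjusted over the list alone; median 1.06, camera adjusted p = 9.92e-23, adjusted p = 0.016 with an estimated correlation), with FMO1 (AT1G19250), required for systemic acquired resistance, at 4.59 ± 0.50 and DLO1 at 2.24 ± 0.17. Autophagy genes were higher in 12 of 42 and lower in 1, ATG2 itself (16 and 1 adjusted over the list alone; median 0.40, camera adjusted p = 2.15e-07, adjusted p = 0.016 with an estimated correlation), with ATG8H at 2.71 ± 0.19 and APG8A at 1.22 ± 0.14. Jasmonate genes were higher in 10 of 28 (10 adjusted over the list alone; camera adjusted p = 1e-05, adjusted p = 0.0451 with an estimated correlation). PR4 differed by 1.60 ± 0.21. Pattern-triggered immunity had 7 of 16 higher (7 adjusted over the list alone; camera adjusted p = 1e-05, adjusted p = 0.0287 with an estimated correlation). WRKY18 differed by 1.42 ± 0.18. Glucosinolate genes had 6 of 22 higher and 0 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.509 with an estimated correlation). CYP79B2 (AT4G39950) differed by 1.56 ± 0.20. Epidermis markers were lower in 5 of 10 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000711, adjusted p = 0.034 with an estimated correlation). CER1 differed by -0.79 ± 0.15.

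Photosynthesis genes were not called between genotypes under TYMV, with 1 of 46 higher and 2 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.3). Besides SAG12, the largest increases were AT5G46960 (at least 63.8-fold higher) and the polygalacturonase gene PGAZAT (AT2G41850, 5.96 ± 0.42). AT2G01422 was again lower (0.282 ± 0.489 against 66.7 ± 10.3 CPM, ratio interval 72.3 to 2170). AT4G09430 (-5.38 ± 1.29) and the TCV-abundant CIPK16 (-3.98 ± 0.79) followed, but without Col-0 TYMV replicate 1 they stood at -2.09, no longer called, and -1.40, and AT4G09430 was also not called without atg2-2 TYMV replicate 3 (edgeR adjusted p = 0.063). Over all tested genes edgeR called 1907 genes, 1115 higher and 792 lower, and 7 lists, with 1125 genes without atg2-2 TYMV replicate 3. On the log2(TPM + 1) scale the split was 1357 higher and 352 lower, and without the filter on low counts it was 1163 higher and 1180 lower.

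**Figure D4:**
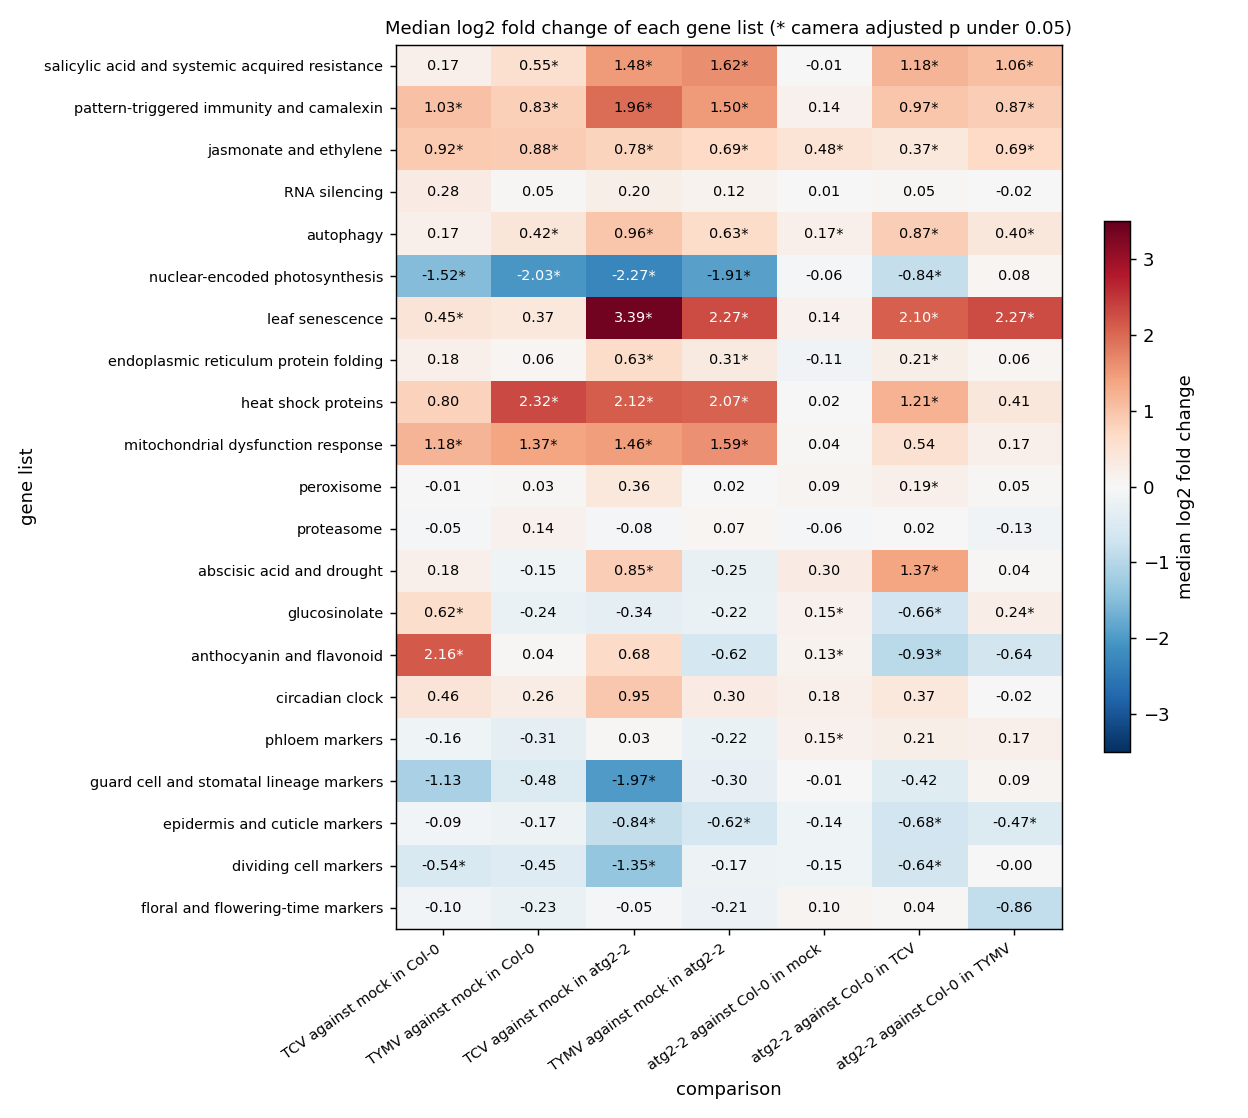
Median log2 fold change (colour and printed value) of the tested members of 21 fixed gene lists (y axis) in 7 comparisons (x axis), with an asterisk where camera gave an adjusted p under 0.05 at the preset correlation. Photosynthesis is lower in each of the 4 comparisons of virus with mock (-1.52, -2.03, -2.27 and -1.91), and senescence has its highest median, 3.39, in TCV against mock in atg2-2.

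The interaction of TCV with genotype tested whether the change from mock to TCV differed between genotypes. The amount of virus was not measured, so a different response and a different level of infection cannot be told apart. Senescence genes responded more in atg2-2, with 11 of 21 called higher (12 adjusted over the list alone; median 2.3, camera adjusted p = 7.67e-15, adjusted p = 0.0471 with an estimated correlation), among them NYE1 (3.92 ± 0.41) and NYC1 (2.3 ± 0.26). Autophagy genes had 10 of 42 higher (12 adjusted over the list alone; median 0.69, camera adjusted p = 1.46e-08, adjusted p = 0.0299 with an estimated correlation), with ATG8H at 4.25 ± 0.38 and ATG8E at 2.02 ± 0.28. Salicylic acid genes had 12 of 28 higher (20 adjusted over the list alone; median 1.12, camera adjusted p = 2.92e-12, adjusted p = 0.0607 with an estimated correlation), with DLO1 at 3.45 ± 0.31 and PBS3 at 3.67 ± 0.52. Photosynthesis genes had 30 of 46 lower (40 adjusted over the list alone; median -0.83, camera adjusted p = 2.26e-20, adjusted p = 0.159 with an estimated correlation), with RBCS1A (AT1G67090) at -1.46 ± 0.20. Anthocyanin genes had 5 of 12 lower (6 adjusted over the list alone; camera adjusted p = 0.000378, adjusted p = 0.0595 with an estimated correlation) and glucosinolate genes 6 of 22 (10 adjusted over the list alone; camera adjusted p = 0.000243, adjusted p = 0.225 with an estimated correlation), with IMD1 at -1.63 ± 0.31. Epidermis markers had 4 of 10 lower (6 adjusted over the list alone; camera adjusted p = 0.00165, adjusted p = 0.0607 with an estimated correlation), with LP1 at -1.25 ± 0.19.

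Abscisic acid genes had 2 of 16 higher (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.72e-05, adjusted p = 0.0702 with an estimated correlation), RD20 at 5.99 ± 0.54 and RD26 at 2.43, the latter lost in 12 of 25 alternatives. Pattern-triggered immunity had 3 of 16 (4 adjusted over the list alone; camera adjusted p = 0.000461, adjusted p = 0.0679 with an estimated correlation), endoplasmic reticulum folding 3 of 23 (5 adjusted over the list alone; camera adjusted p = 0.00132, adjusted p = 0.113 with an estimated correlation), including BI1 at 0.81 ± 0.17, and heat shock 0 of 19 (0 adjusted over the list alone; camera adjusted p = 0.00141, adjusted p = 0.225 with an estimated correlation). Among the genes named by the fixed rule was AT3G46490 (-7.50 ± 1.18), which had 0 counts in atg2-2 TCV, so its fitted value is no bound. The edgeR test called 1361 genes, 577 higher and 784 lower, and 11 lists. The gene count was 778 without Col-0 mock replicate 2, 804 without atg2-2 mock replicate 1 and 886 without atg2-2 mock replicate 2, and the split was 457 higher and 981 lower on the log2(TPM + 0.1) scale.

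For TYMV the interaction was called in fewer genes. Senescence had 5 of 21 higher (10 adjusted over the list alone; median 1.62, camera adjusted p = 2.16e-21, adjusted p = 0.022 with an estimated correlation). ASN1 (4.41 ± 0.59) and SEN1 (AT4G35770, 3.87 ± 0.56), a gene induced in darkness and senescence, changed in opposite directions in the genotypes, with ASN1 at 2.76 in atg2-2 and -1.65 in Col-0, and SEN1 at 1.38 and -2.49. Salicylic acid had 6 of 28 higher (19 adjusted over the list alone; median 0.98, camera adjusted p = 2.16e-21, adjusted p = 0.022 with an estimated correlation), with DLO1 at 2.32 ± 0.29. Autophagy had 2 of 42 higher, ATG8H (2.71 ± 0.35) and APG8A (1.14, lost in 6 of 26 alternatives) (3 adjusted over the list alone; camera adjusted p = 0.00341, adjusted p = 0.134 with an estimated correlation). Pattern-triggered immunity (3 adjusted over the list alone; camera adjusted p = 0.00341, adjusted p = 0.134 with an estimated correlation) and endoplasmic reticulum folding (1 adjusted over the list alone; camera adjusted p = 0.0385, adjusted p = 0.436 with an estimated correlation) were called upward and epidermis markers downward (2 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00341, adjusted p = 0.0986 with an estimated correlation), with 0 members passing in each over all genes. The edgeR test called 97 genes, 87 higher and 10 lower, and 6 lists. The gene count ran from 17 without atg2-2 mock replicate 1 to 159 without Col-0 TYMV replicate 1, with 38 without Col-0 mock replicate 2, 43 without atg2-2 mock replicate 2 and 55 without atg2-2 TYMV replicate 3. DESeq2 called 212, log2(TPM + 1) 201, only the compared groups 61 and no filter 561. The split of the calls was not stable, with 274 higher and 287 lower without the filter and 95 higher and 64 lower without Col-0 TYMV replicate 1.

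The viruses were compared directly within each genotype. In Col-0, TCV left photosynthesis genes higher than TYMV did in 33 of 46 (35 adjusted over the list alone; median 0.53, camera adjusted p = 1.46e-09, adjusted p = 0.584 with an estimated correlation), with the plastocyanin gene PETE1 (AT1G76100) at 326 ± 23.4 against 130 ± 14.3 CPM (1.33 ± 0.11, edgeR adjusted p = 2.2e-08). Anthocyanin genes were higher in TCV in 6 of 12 (6 adjusted over the list alone; camera adjusted p = 0.000348, adjusted p = 0.13 with an estimated correlation), with DFR at 4.79 ± 0.49 and GSTF12 at 4.59 ± 0.41. Glucosinolate genes were higher in 13 of 22 and lower in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 0.000348, adjusted p = 0.584 with an estimated correlation), with CYP79B3 at 3.51 ± 0.23 and TGG2 at -1.40 ± 0.14. Heat shock genes were lower in 7 of 19 and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0299, adjusted p = 0.584 with an estimated correlation). HSP101 (AT1G74310) differed by -2.61 ± 0.54. ATG2 was lower in TCV (-1.06 ± 0.24, edgeR adjusted p = 0.0022). The largest differences were in virus-abundant genes, AT1G18000 (at least 427-fold higher in TCV) and AT4G04650 (at least 380-fold lower), with AT3G44810, in neither set, at least 269-fold lower. The edgeR test called 5226 genes, 2690 higher and 2536 lower in TCV, and 4 lists. On the log2(TPM + 1) scale the split was 1895 higher and 3749 lower.

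In atg2-2 the order of the photosynthesis list was the other way, with 25 of 46 lower in TCV than in TYMV and 0 higher (26 and 1 adjusted over the list alone; median -0.37, camera adjusted p = 0.000298, adjusted p = 0.713 with an estimated correlation), and PSAN differed by -1.25 ± 0.15. Abscisic acid genes were higher in TCV in 14 of 16 (15 adjusted over the list alone; median 1.22, camera adjusted p = 8.66e-06, adjusted p = 0.14 with an estimated correlation), with RD20 at 2.53 ± 0.21 and the dehydrin gene COR47 (AT1G20440) at 1.33 ± 0.13. Senescence genes were higher in 13 of 21 and lower in 2 (14 and 2 adjusted over the list alone; median 1.03, camera adjusted p = 0.000947, adjusted p = 0.346 with an estimated correlation), with SAG29 at 2.99 ± 0.24 and NYE1 at 2.09 ± 0.19. Dividing cell markers were lower in 7 of 12 (8 adjusted over the list alone; camera adjusted p = 0.00535, adjusted p = 0.14 with an estimated correlation). PCNA1 differed by -1.97 ± 0.32. The largest differences were the TCV-abundant AT2G22050 (at least 4740-fold higher) and AT3G01795 (at least 1220-fold higher), and AT1G06330 (at least 60.2-fold lower). The edgeR test called 6168 genes, 3106 higher and 3062 lower in TCV, and 4 lists. On the log2(TPM + 1) scale the split was 1896 higher and 6547 lower.

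The responses to the viruses shared genes. In Col-0, 1961 genes were called in the same direction against mock with both viruses, 681 higher and 1280 lower, and 87 in opposite directions, where independent lists would share 270 and 272. In atg2-2 the numbers were 3430, 1534 higher and 1896 lower, with 82 opposite and 528 and 496 for independent lists. Fold changes of the viruses correlated across genes with Pearson r of 0.445 in Col-0 (covariance 0.949) and 0.595 in atg2-2 (covariance 1.58). Both comparisons use the same mock libraries, and in 20 simulations of unchanged groups the mean r was 0.56 and 0.54, the mean covariance 0.20 and 0.19, and at most 2 and 6 genes were called in the same direction. Part of the excess may come from the shared controls. Fits with separate mock libraries held more genes (19165 and 19171), and fewer mock libraries lower counts by construction, so these fits cannot decide this. With each virus against 1 mock library of its own, an alternative added after the data were seen, 1009 and 1067 genes were shared in Col-0 in the assignments of the mock libraries (covariance 0.978 and 0.956) and 2150 and 2114 in atg2-2 (covariance 1.63 and 1.66). Independent lists would there share 101 higher and 117 lower, 109 and 119, 224 and 263, and 222 and 266. Without Col-0 mock replicate 1 the overlap in Col-0 was 1094. Between genotypes, a comparison added after the data were seen, 4234 genes changed in the same direction with TCV (52 opposite) and 2627 with TYMV (11 opposite), where independent lists would share 603 higher and 563 lower, and 236 higher and 239 lower.

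Lists that were not called against mock in any of the 4 comparisons complete the account. Proteasome genes had 4 of 31 up and 3 down in Col-0 with TCV (4 and 3 adjusted over the list alone; camera adjusted p = 0.935) and 6 up and 1 down with TYMV (6 and 1 adjusted over the list alone; 0.123). Peroxisome genes had 8 of 35 up and 7 down with TCV in Col-0 (9 and 7 adjusted over the list alone; camera adjusted p = 0.6). Circadian clock genes had 4 of 15 up and 1 down with TCV (4 and 1 adjusted over the list alone; camera adjusted p = 0.0754), the evening complex gene PCL1 (AT3G46640) rising by 1.98 ± 0.18. Phloem markers had 1 of 10 up and 3 down with TCV in Col-0 (1 and 3 adjusted over the list alone; camera adjusted p = 0.6), and floral and flowering-time markers had 0 of 7 changed (0 adjusted over the list alone; 0.835). RNA silencing in the mutant had 5 of 17 up with TCV (5 adjusted over the list alone; camera adjusted p = 0.11). No list called by camera changed direction with RLE, DESeq2 or TPM scaling. TPM scaling moved the median of all genes by over 0.1 in 6 comparisons. It moved from 0.02 to 0.19 and from 0.01 to 0.26 in TYMV against mock in Col-0 and atg2-2, and from 0.02 to -0.09 in TCV against mock in atg2-2. Between genotypes in TYMV it moved from -0.06 to 0.07, and in TCV against TYMV from -0.03 to -0.20 in Col-0 and to -0.40 in atg2-2. The move was -0.100 in the TCV interaction. In no called list did the median, mean and test differ in sign, and among lists not called the median and mean did in 0 to 7 of 21 per comparison.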

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

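The tests of the TCV-abundant genes, of Col-0 TYMV replicate 1 and of the interaction against simulated counts were chosen only after the results were seen, and the thinning and the splits were chosen before.

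An interaction test in edgeR asked whether the effect of a virus differed between genotypes. For TCV it called 1361 genes and for TYMV 97. Camera adjusted p for the TCV interaction was 2.92e-12 for salicylic acid, 0.000461 for pattern-triggered immunity, 1.46e-08 for autophagy, 2.26e-20 for photosynthesis, 7.67e-15 for leaf senescence, 0.00132 for endoplasmic reticulum folding, 0.00141 for heat shock proteins, 2.72e-05 for abscisic acid, 0.000243 for glucosinolate, 0.000378 for anthocyanin and 0.00165 for epidermis markers. With an estimated correlation only autophagy (adjusted p = 0.0299) and leaf senescence (0.0471) were called, and the others stood at 0.0607, 0.0679, 0.159, 0.113, 0.225, 0.0702, 0.225, 0.0595 and 0.0607 in that order. Camera adjusted p for the TYMV interaction was 2.16e-21 for salicylic acid and for leaf senescence, 0.00341 for pattern-triggered immunity, autophagy and epidermis markers, and 0.0385 for endoplasmic reticulum folding. With an estimated correlation salicylic acid and leaf senescence were called (adjusted p = 0.022 each), and pattern-triggered immunity (0.134), autophagy (0.134), epidermis markers (0.0986) and endoplasmic reticulum folding (0.436) were not.

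Single genes whose TCV effect differed between genotypes, with their interaction log2 fold change, were DLO1 (3.45), PBS3 (3.67), ATG8H (4.25), ATG8E (2.02), RBCS1B (-1.78), RBCS1A (-1.46), NYE1 (3.92), NYC1 (2.3), BI1 (0.81), RD20 (5.99), IMD1 (-1.63), TGG1 (-1.12), LP1 (-1.25), KCS6 (-1.34), AT3G46490 (-7.50) and AT3G50560 (-4.84), which were called in each alternative that gave a value. Calls lost in some alternatives were AT5G64190 (10.69, lost in 4 of 25, highest adjusted p 1), AT3G22620 (10.64, 12 of 24, 1), AT14A (-5.33, 11 of 26, 0.17), WAK1 (1.01, 4 of 26, 0.13), CYP71A13 (7.12, 5 of 23, 0.26), RD26 (2.43, 12 of 25, 0.18) and LDOX (-3.15, 4 of 26, 0.14). NAC3 (9.71) was lost without Col-0 mock replicate 2 (adjusted p = 0.058), ATERDJ3A (3.25) without atg2-2 mock replicate 1 (3.01, adjusted p = 0.063) and TT4 (-1.29) without Col-0 mock replicate 2 (-1.18) or atg2-2 mock replicate 2 (-0.98). For TYMV they were DLO1 (2.32), ATG8H (2.71), ASN1 (4.41) and SEN1 (3.87), called in each alternative, and DIN2 (9.0, lost in 4 of 25, highest adjusted p 1), AT5G43570 (8.22, 5 of 25, 1), MIOX4 (7.83, 11 of 25, 0.35), AT1G61600 (-2.67, 14 of 25, 0.55), MIPS1 (-1.79, 16 of 26, 0.27) and APG8A (1.14, 6 of 26, 0.24). PBS3 (2.76) was lost without Col-0 mock replicate 2 (2.39), atg2-2 mock replicate 1 (2.68) or atg2-2 mock replicate 2 (2.86), and TCH4 (-1.76) without Col-0 mock replicate 2 (-1.84) or atg2-2 mock replicate 2 (-1.44). The fitted values of AT5G64190, AT3G22620, NAC3, AT3G46490, CYP71A13 and DIN2 depend on the prior count because a group had 0 counts.

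The 107 genes that were abundant in every TCV library and far lower in mock are the first pattern. A host response of like size to both viruses is argued against for these genes, because the median log2 fold change was 0.56 in TYMV against mock in atg2-2 (quartiles -0.02 and 1.79), far under the lower quartile of 7.42 in TCV against mock there. The rule chose these genes for high counts in the same TCV libraries, so part of this contrast was fixed in advance. Reads not made from transcripts of these genes, such as viral RNA primed at A-rich stretches, stay open. Only annotated host transcripts were searched for A runs, and no viral sequence was, so the test cannot decide this. Of the genes, 12.1% had a run of at least 12 A in the longest transcript. The 95% range in 1000 draws matched on length alone was 1.87 to 10.3%. Most of the genes had no such run. A weaker response to TYMV in part of the genes stays open. A host response to TCV with ordinary variation stays open too: the median SD across TCV libraries was 0.25, below the draws (0.26 to 0.36), but 201 genes chosen by their mean had 0.36 (draws 0.27 to 0.35), and the forms of this test and of the test of like size were revised after their first outcome.

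Col-0 TYMV replicate 1, where the TCV-abundant genes took 0.402% of counts, is the second pattern. A host response to TYMV common to its libraries is argued against, because the median excess over mock in the other 5 TYMV libraries was 0.07% of the TCV level, against 1.4% in this library. This library was singled out for its high share, so part of that contrast was fixed in advance. A small share of reads or RNA from a TCV sample stays open and could account for the excess, since the excess was a similar percentage of the TCV level across genes (quartiles 1.1 and 2.4%, ratio 2.27). How such material would have entered was not tested. The TYMV-abundant genes took 1.62% of counts there against 4.69 and 3.98% in the other Col-0 TYMV libraries, a gap too large for dilution by such a share, and its cause was not tested.

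The third pattern is the difference between 7 genes called between genotypes in mock and the many called under virus. Fewer libraries or other depth in mock are argued against as the whole cause: with 2 libraries against 2 thinned to a total of 1338515, mock gave 39 genes, TYMV at the lowest 336 (9 choices) and TCV 1678 to 3329. A virus effect that differs between genotypes stays open as a hypothesis. The TCV interaction test called 1361 genes, against at most 1 in 10 simulations without an interaction. That count restates the pattern in the same libraries, and the simulations held no difference in infection, so it cannot separate the causes. Viral RNA was not measured, and the labels do not say whether genotypes or treatments were grown or inoculated together. A difference in infection, for example between trays, may therefore also contribute and was not tested.

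Groups of 3 against 3 have 10 splits, so the share as large is never under 0.1. Other splits mix the true groups, so their counts are no null reference. Fits held the compared groups alone, unlike the main fit. The genotypes in TCV gave 3921 genes against at most 8 in another split (1 of 10 as large) and 15 lists against at most 9 (1 of 10). The genotypes in TYMV gave 1589 genes against 0 (1 of 10) and 7 lists against 7 (2 of 10). TCV against TYMV gave 4471 genes against 0 (1 of 10) and 3 lists against 4 (3 of 10) in Col-0, and 5330 genes against 0 (1 of 10) and 4 lists against 9 (6 of 10) in atg2-2.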

How the results depend on the processing

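The fits without virus-abundant genes, the fits with genes of at least 5 CPM in mock, the overlaps between genotypes and the overlaps with separate mock libraries were chosen only after the results were seen. Of the log2 fold changes of named genes, the direction and side of the threshold were kept in 315 of 318 with DESeq2, 319 of 320 with RLE, 317 of 320 without the filter, 319 of 319 with the stricter filter, 307 of 317 with the compared groups alone, 306 of 320 on log2(TPM + 1), 298 of 320 on log2(TPM + 0.1), 299 of 299 without virus-abundant genes, 247 of 247 with genes of at least 5 CPM in mock, and 274 of 320 whichever library was left out. Replicate numbers do not pair the libraries: within-group residuals of libraries sharing a number correlated at -0.069 to 0.055, and 4 of 16 correlated best with their own number. Of the named log2 fold changes, 315 of 320 were kept with the number as a block. With the number as a block the calls were 4689 and 3522 genes for TCV and TYMV against mock in Col-0, 7977 and 4119 in atg2-2, and 8, 4471 and 1761 between genotypes in mock, TCV and TYMV, and no count moved by over 1.5 times. Lists called with the block were 6 and 7 for TCV and TYMV against mock in Col-0, 13 and 10 in atg2-2, 4, 14 and 7 between genotypes in mock, TCV and TYMV, 12 and 5 for the TCV and TYMV interactions, and 4 and 4 for TCV against TYMV. The camera adjusted p of the lists whose call changed was 0.071 for pattern-triggered immunity and 0.091 for leaf senescence in TCV against mock in Col-0, 0.073 for phloem markers between genotypes in mock, 0.057 for endoplasmic reticulum folding in the TYMV interaction and 0.049 for peroxisome genes in the TCV interaction. Depth limits genes near the floor and small changes. The simulations in the methods give the recovery of small changes in genes of at least 10 CPM where few genes change, and none for genes near the floor.

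Values that moved follow, and the cause was not tested except where fewer libraries or an added threshold explain it by construction. Genotype calls in mock numbered 18 with DESeq2, 89 without the filter and 23 with the compared groups alone, and TYMV interaction calls 212, 561 and 61, with 201 on log2(TPM + 1). With a log2 fold change of at least 1 the calls were 3026 (TCV in Col-0), 2277 (TYMV in Col-0), 2679 (TYMV in atg2-2), 2325 and 1122 (genotypes in TCV and TYMV), and 2984 and 3653 (TCV against TYMV in Col-0 and atg2-2), with splits of 1425 higher and 852 lower (TYMV in Col-0) and 1390 and 935 (genotypes in TCV) and overlaps of 867 and 1987 between viruses and 2532 and 1439 between genotypes. With an estimated correlation, lists called were 0 for TCV and TYMV against mock in Col-0, 0 for TCV against mock in atg2-2, 0 for genotypes in mock, 0 and 0 for TCV against TYMV, 1 for genotypes in TCV and 2 and 2 for the TCV and TYMV interactions. With fry they were 14 for TCV against mock in Col-0, 0 for genotypes in mock, and 11 and 12 for TCV against TYMV. ATG2, not called there, turned to -0.19 and -0.29 on the TPM scales and -0.01 without atg2-2 TCV replicate 3 for TCV against TYMV in atg2-2 (highest 0.28 without atg2-2 TCV replicate 2), and to -0.18, -0.04 and -0.02 without Col-0 mock replicate 1, Col-0 TCV replicate 1 or Col-0 TCV replicate 2 for TCV against mock in Col-0 (highest 0.27 without Col-0 mock replicate 2).

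Leaving out each library in turn gave ranges of 3319 (without Col-0 mock replicate 1) to 5090 genes and 3 to 10 lists for TCV in Col-0, 2268 (without Col-0 mock replicate 1) to 3953 and 4 to 8 for TYMV in Col-0, and 6503 to 8372 and 12 to 13 for TCV in atg2-2. They were 2811 (without atg2-2 mock replicate 2) to 4567 and 10 to 11 for TYMV in atg2-2. Between genotypes they were 5 to 23 (without Col-0 mock replicate 2) and 1 to 9 in mock, 3676 to 4664 and 14 to 15 in TCV, and 1125 (without atg2-2 TYMV replicate 3) to 1937 and 7 to 8 in TYMV. The interactions ranged over 778 (without Col-0 mock replicate 2) to 1511 and 11 to 13 for TCV, and 17 (without atg2-2 mock replicate 1) to 159 (without Col-0 TYMV replicate 1) and 4 to 8 for TYMV. TCV against TYMV ranged over 4403 to 5295 and 3 to 4 in Col-0, and 5055 to 6195 and 4 to 6 in atg2-2. The overlap of the viruses was 1094 (without Col-0 mock replicate 1) to 1963 in Col-0 and 2288 to 3476 in atg2-2, with 1009 and 1067 in Col-0 and 2150 and 2114 in atg2-2 when each virus had its own mock library, and that of the genotypes 2915 to 4258 with TCV and 1796 to 2671 with TYMV.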

Other observations

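The gene families here were chosen only after the data were seen, and the test of the sulfur list was chosen before its result. Among 121 families of genes sharing a symbol, WRKY transcription factors were higher in TCV against mock in atg2-2 in 29 of 46 and lower in 1 (median 1.71, camera adjusted p = 3.5e-06, adjusted p = 0.071 with an estimated correlation). NAC transcription factors were higher in 28 of 40 there (median 1.88, camera adjusted p = 3.5e-06, adjusted p = 0.062 with an estimated correlation) and in 17 of 40 in TYMV against mock in atg2-2 (median 1.35, camera adjusted p = 1.3e-07, adjusted p = 0.032 with an estimated correlation). In the TCV interaction NAC genes had 6 of 40 higher (median 0.90, camera adjusted p = 5.9e-06, adjusted p = 0.04 with an estimated correlation). PTAC genes, nuclear genes for proteins of the plastid transcriptionally active chromosome, were lower in TCV against mock in atg2-2 in 14 of 14 (median -1.47, camera adjusted p = 3.5e-06, adjusted p = 0.065 with an estimated correlation).

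FLA genes, which encode fasciclin-like arabinogalactan proteins, were lower in atg2-2 than Col-0 under TCV in 7 of 14 (median -1.54, camera adjusted p = 2.8e-05, adjusted p = 0.048 with an estimated correlation). KCS genes, of very-long-chain fatty acid synthesis, had 6 of 15 lower in the TCV interaction (median -0.93, camera adjusted p = 1.1e-05, adjusted p = 0.04 with an estimated correlation). In TYMV against mock in atg2-2, SAUR genes were lower in 10 of 15 (median -1.66, camera adjusted p = 0.0021, adjusted p = 0.048 with an estimated correlation) and IAA genes in 9 of 18 (median -0.92, camera adjusted p = 0.00015, adjusted p = 0.042 with an estimated correlation).

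Between genotypes, 4 genes were called in the same direction in mock, TCV and TYMV: AT1G75945 (4.74, 7.47 and 5.04), GAMMA-VPE (1.36, 2.06 and 1.76), AT2G01422 (-6.12, -6.50 and -7.78) and AT5G24240 (-5.17, -2.65 and -3.85). In mock, the call of AT1G75945 was lost without Col-0 mock replicate 1 (4.32) or atg2-2 mock replicate 2 (4.41).

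APR1, APR3 and AT1G04770, which belong to the response of plants to sulfate starvation, were among the 7 genes called between genotypes in mock. As a hypothesis, a sulfur-starvation response may be higher in atg2-2. A list of 14 other genes of this response, 12 of them tested, was higher in mock in 12 of 12 (median 1.3, camera p = 1.8e-16, and p = 5.7e-06 with an estimated correlation), with 0 called by edgeR. The list was chosen after the calls above were seen in the same mock libraries. Genes of one response can move together, so it is no independent support. It was not tested with single mock libraries left out. Between genotypes under TYMV the limma camera test gave a p of 6.8e-05 (median 0.60) and under TCV 0.21 (median 0.39), and it gave 9.1e-07 in TCV against mock in Col-0 (median 1.74). In that last comparison edgeR called 9 of 12 higher.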
